A study of Parhyale hawaiensis with 16 samples.

How the data were processed

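RNA was measured in whole embryos of the amphipod crustacean Parhyale hawaiensis at 4 developmental stages, S13, S19, S21 and S23. Per the labels, the embryos were of an isogenic line, total RNA was isolated with the Zymo Direct-Zol kit, and 12 libraries for short reads, 3 per stage, were made with the SMART-Seq v4 kit. The labels give no strand for these libraries and do not say whether the 3 libraries of a stage came from separate clutches. Without a stated strand, reads of overlapping or antisense genes cannot be told apart. The labels also list 4 Nanopore libraries, 1 per stage, which are not analysed here. Trim Galore, FastQC, cutadapt, HISAT2, kallisto, RSEM and DESeq2 are named in the submitters' processing notes, without versions.

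The 3 tables of stage comparisons, S19 against S13, S21 against S19 and S23 against S21, are results that the authors computed from their counts. Per the file headers they hold, for each gene, the mean normalized count over the 6 libraries of both stages, the log2 fold change, its standard error, a Wald statistic, a p-value and an adjusted p-value, which are the result columns of DESeq2. The deposited log2 fold changes have the later stage as numerator, are not shrunken, and differ in scale between tables for the stage they share, as separate fits per pair would. The deposited score of each gene is the Wald statistic, the fold change divided by its standard error, and the authors' adjusted p-value is that of DESeq2 (Benjamini-Hochberg), blank for part of the genes. The numerator was checked by rebuilding the mean count of S19 and of S21 from both tables that hold it. Read this way, the log2 ratio of the S19 means from both tables lay between -0.19 and -0.18 for the central 90% of 9929 genes. With the numerator of the first table turned round it lay between -1.76 and 1.09. The design allowed for counts per library, but the deposited tables held the authors' comparisons, so their test was used. Without values per library the depth of each library is unknown, no test was fitted to counts here and no replicate was left out. The sum of the mean normalized counts was 1.89e+07, 1.79e+07 and 1.72e+07 in the 3 tables.

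Genes past the authors' adjusted p of 0.05 are called higher or lower at the later stage. Mean counts of a single stage were computed from the mean of both stages and the fold change. A floor of 3 counts over the 3 libraries of a stage, or 1 normalized count per library, was set, and the fold of a gene below it in 1 stage is given as a lower bound ("at least"). The p-values measure the spread between these libraries.

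Gene names, descriptions and functional categories (COG) came from the authors' eggNOG annotation of the Mikado gene models, made with emapper 1.0.3-40-g41a8498 per the file headers. Of 49780 genes, 17947 had an annotation and 5619 a name. The names are those of the best-matching orthologue, so several gene models can share one, and counts of such models are uncertain where the authors' counting could split reads between them. A total of 19 lists of genes was fixed before the data were examined: Hox, segmentation, appendage patterning, neurogenesis, synapse and neurotransmission, muscle structure, myogenic and mesoderm regulators, cuticle and chitin, DNA replication and cell cycle, cytosolic ribosomal proteins, oxidative phosphorylation, eye and photoreceptor, digestive enzymes, hemocyanin and phenoloxidase, germ cell, Wnt, Notch, ecdysone and moulting, and genes of other organisms. Each list was tested with cameraPR of limma 3.58.1 in R 4.3.3, a two-sided competitive test on the deposited statistic with a preset correlation between genes of 0.01. Benjamini-Hochberg adjustment was made over the 19 lists of a comparison, and in the same way over 22 COG categories with at least 20 tested genes. The correlation between genes cannot be estimated from 1 statistic per gene, so a preset of 0.05 was the alternative. Members that share only a symbol or a word with their list, such as tramtrack (ttk) with the kinase TTK, were set apart and the lists tested again without them.

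Named genes followed a rule fixed before the data were examined. In each comparison, these were the 6 genes with the largest rise and the 6 with the largest fall among called genes with a name and a mean normalized count of at least 100. Added were up to 2 called members per list and direction with the largest changes, and every tested member of the Hox list. Some of these genes are left out of the text for length.

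Consecutive comparisons share the libraries of a stage, so overlaps are given beside the number for independent lists, and covariances of fold changes beside 100 simulations of unchanged groups that share a stage. The set test, the rebuilt stage means and the simulation were tested on simulated data. In each comparison, 40 of 40 shifted lists were called in the right direction. Of 340 unshifted lists, 1 was called for S19 against S13, 1 for S21 against S19 and 2 for S23 against S21. The simulated statistics were independent between genes and the shifts were large. These counts therefore do not show how correlation between genes would affect the calls. The simulated correlation of a shared stage was -0.50 at equal variances, where the known answer is -0.5.

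The annotation files hold positions on the genome build phaw_5.0, given 1-based. They cover MAKER gene models, Mikado loci, and alignments of an earlier transcriptome, of the transcripts of Kao and co-workers and of cloned sequences, of which the file headers name GMAP 2017-10-30 for the transcriptome and the transcripts of Kao and co-workers. Overlaps were counted with bedtools 2.31.1 as at least 1 shared base on the same strand. Splice junctions and the count of spliced alignments at each, over all libraries together, came from the authors' Portcullis tables, which per the file headers were made with version 1.2.0 and hold a score per passed junction. The peak files hold merged regions with their type, nearest gene and distance. Their assay and peak caller are not given in the sources used here, and the score per peak is the authors' and was used only to rank peaks. Shares carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only. Other computations used pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

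The alternatives tried were an adjusted p of 0.01, a log2 fold change of at least 1, mean counts of at least 10 or 100, adjustment over the 3 comparisons together or over every raw p, fold changes centred on the median of genes with a mean of at least 100, and annotated genes alone. For lists and categories they were the correlation of 0.05, ranks, 1 gene model per name, a mean count of at least 10 and Fisher's exact test of the calls. For the annotation they were an e-value under 1e-10, shares per transcript, 50% coverage, either strand, junctions with at least 10 reads or canonical motifs, and peaks of the higher-score 50% or within 10 kb of a gene. The lists without members that share only a symbol or a word, and a correction of the statistic for transcript length, were chosen after seeing the data.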

Results

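The data describe gene expression in whole Parhyale hawaiensis embryos at stages S13, S19, S21 and S23, with 3 short-read libraries per stage, and a genome annotation made with these libraries. The values of the stage comparisons are those of the authors' deposited table for each pair of consecutive stages, as log2 fold changes of the later over the earlier stage with their standard errors (SE) from 3 libraries per stage. Of 49780 genes, 14007 were called in at least 1 interval and 626 in all 3. The number of called genes grew along the series, from 3498 for S19 against S13 to 6433 for S21 against S19 and 8526 for S23 against S21. The number of genes with an adjusted p grew too (33913, 37222 and 43330), and the share called was 10.3%, 17.3% and 19.7%. The median absolute log2 change of called genes was 2.27, 1.79 and 1.78 in the same order. Whether more genes changed or the libraries varied less was not tested.

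**Figure D1:**
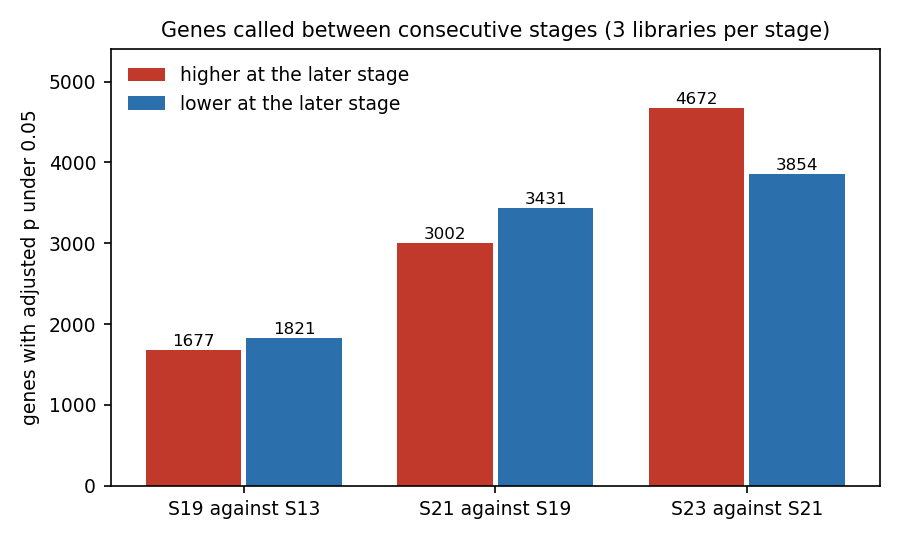
Genes past an adjusted p of 0.05 in the authors' DESeq2 tables (y axis, number of genes) for each pair of consecutive stages (x axis), split into genes higher and lower at the later stage. The bars run from 1677 higher and 1821 lower genes for S19 against S13 to 4672 higher and 3854 lower genes for S23 against S21.

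The first comparison asks what changed between S13 and S19. Regulators of neurogenesis rose, together with genes of DNA replication and the cell cycle. Among the Hox genes, which give segments along the body axis their identity, Abd-B, Ubx, Antp and Scr were higher at S19. The homeobox gene Dll, which patterns the distal limb, and Pros (prospero), a regulator of neural precursors, also rose. The pair-rule gene Prd and a model of eve fell.

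The Hox list rose, with 4 of 8 tested members higher and none lower (4 and 0 adjusted over the list alone), and adjusted p = 0.000726 by cameraPR. The call was lost with ranks of the statistic (adjusted p = 0.283 by cameraPR). Abd-B (mikado.phaw_50.282695aG444) rose by 6.07 ± 0.81 (SE) and Ubx (mikado.phaw_50.282695aG455) by 3.87 ± 0.61 on the log2 scale in the authors' deposited table. Antp (mikado.phaw_50.282695aG456) rose by 2.52 ± 0.47 and Scr (mikado.phaw_50.282695aG460) by 1.97 ± 0.52 in the authors' deposited table. The adjusted p of these 4 genes in the authors' deposited table lay between 6.45e-12 and 0.00300 (DESeq2). The other members did not pass in the authors' deposited table, with log2 values of 0.05 ± 0.89 for abd-A, -0.04 ± 0.44 for lab, -0.54 ± 0.62 for Dfd and -1.92 ± 1.29 for hoxb3. All 8 genes of the list lie on scaffold phaw_50.282695a of build phaw_5.0, in the order Abd-B (24617376 to 24696164), abd-A, Ubx, Antp, Scr, Dfd, hoxb3 and lab (28102330 to 28121063). A model made from a proboscipedia clone (mikado.phaw_50.282695aG482) is also a Hox gene but has another name in the annotation and so is outside the list. Its adjusted p in the authors' deposited table was 0.268, 0.649 and 0.773 in the order of the stages (DESeq2).

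**Figure D2:**
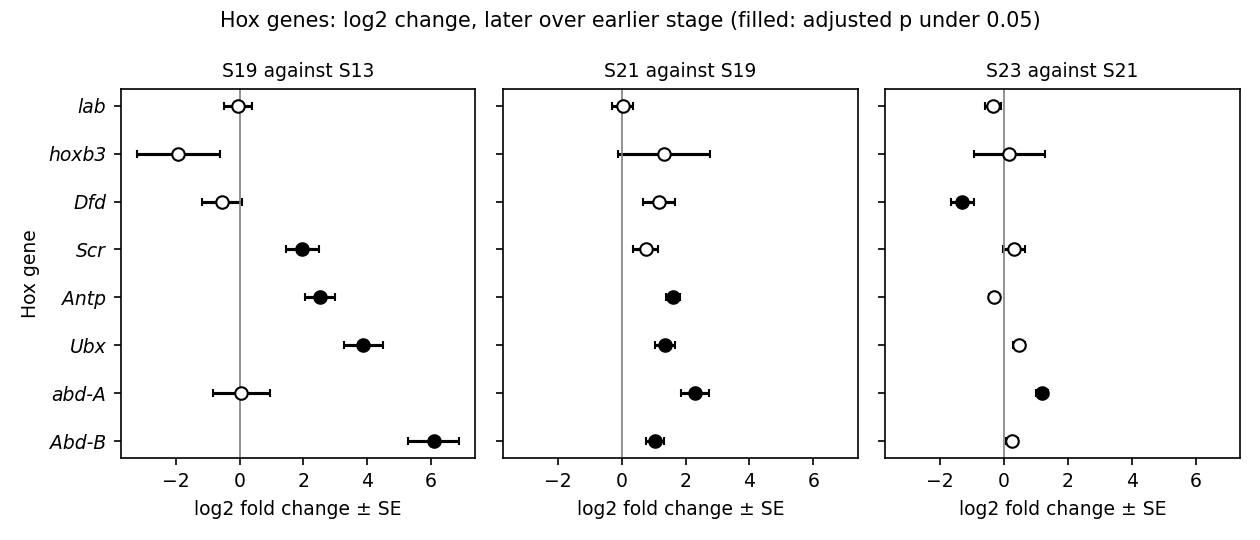
Log2 fold change of each gene of the Hox list, later over earlier stage (x axis, with bars of 1 SE), in the authors' deposited table, with 1 panel per pair of stages and genes in the order lab to Abd-B (y axis). Filled points passed an adjusted p of 0.05. The largest value is that of Abd-B at S19 against S13, 6.07, and abd-A passed at S21 against S19 with 2.31 and at S23 against S21 with 1.19.

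Neurogenesis regulators rose, with a median log2 change of 1.19 and adjusted p = 6.81e-05 by cameraPR. The call was lost with Fisher's exact test of the calls (adjusted p = 0.0664). Of 12 tested members, 3 were higher and none lower (4 and 0 adjusted over the list alone). These were Pros (mikado.phaw_50.283875aG80), with 3.49 ± 0.31, fne (mikado.phaw_50.283869cG242), a neuronal RNA-binding protein, with 4.04 ± 1.12, and neur (mikado.phaw_50.007301aG182), a ubiquitin ligase of Notch signalling, with 1.09 ± 0.23 in the authors' deposited table. Of 13 tested appendage patterning genes, 4 were higher and 1 lower (4 and 1 adjusted over the list alone), with adjusted p = 0.0273 by cameraPR. The call was lost with a preset correlation of 0.05 (adjusted p = 0.0791), with ranks (adjusted p = 0.159) and with 1 gene model per name (adjusted p = 0.0595). In the authors' deposited table Dll (mikado.phaw_50.282654bG562) rose by 2.78 ± 0.37, and bab1 (mikado.phaw_50.283868dG384), a factor of distal leg segments, fell by 1.42 ± 0.44.

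Genes of DNA replication and the cell cycle gave the largest number of higher genes among the lists, with 23 of 60 higher and 3 lower (31 and 4 adjusted over the list alone), a median log2 change of 0.74 and adjusted p = 4.14e-10 by cameraPR. Without the members that share only a symbol, 21 of 56 were higher and 3 lower (adjusted p = 1.19e-08 by cameraPR). The mitotic kinase polo (mikado.phaw_50.283811G66) was at least 23.3-fold higher at S19, counted against the floor at S13. A model of RfC4 (mikado.phaw_50.008125G1), a subunit of the clamp loader, fell by 4.23 ± 0.67, and MCM6 (mikado.phaw_50.283743aG192), of the replicative helicase, fell by 1.54 ± 0.47 in the authors' deposited table. Among 21 segmentation genes, 3 were higher and 2 lower (5 and 2 adjusted over the list alone), and the list did not pass (adjusted p = 0.277 by cameraPR). In the authors' deposited table kni (mikado.phaw_50.283866G145), a gap gene in insects, rose by 4.71 ± 0.55 and EN2 (mikado.phaw_50.283864aG80), an engrailed gene of segment boundaries, by 2.25 ± 0.33. The pair-rule gene Prd (mikado.phaw_50.000214eG128) fell by 2.34 ± 0.31 and eve (mikado.phaw_50.283028bG120) fell by 2.18 ± 0.62 in the authors' deposited table. This eve is the model of the clone eve2. The clone eve1 lies on another model (mikado.phaw_50.283828dG158), with a mean of 0 in this comparison in the authors' deposited table.

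Of 5 tested hemocyanin and phenoloxidase genes, 1 rose (1 adjusted over the list alone), a hemocyanin (mikado.phaw_50.283828aG506) with 3.79 ± 0.73 in the authors' deposited table. Hemocyanin carries oxygen in the blood of crustaceans. The list had adjusted p = 0.0379 by cameraPR, and adjusted p = 0.0782 with a preset correlation of 0.05 or adjusted p = 0.0564 at a mean of at least 10. Fisher's exact test of the higher calls gave the list adjusted p = 0.633. Its median of 3.59 was 2.58 with genes below the floor at their bound. Germ cell genes did not pass as a list (2 of 27 higher, 4 lower, 3 and 5 adjusted over the list alone, adjusted p = 0.426 by cameraPR). The helicase vas (mikado.phaw_50.283743bG306), a marker of germ cells, was at least 36.6-fold lower at S19. The gene Ago3 (mikado.phaw_50.020523dG179), of the piRNA pathway, fell by 3.68 ± 1.21 in the authors' deposited table.

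The remaining lists did not pass, with adjusted p from 0.0571 for ribosomal proteins to 0.889 for ecdysone genes by cameraPR. Under alternatives, ribosomal proteins passed as higher with ranks (adjusted p = 0.00979) and with the statistic corrected for transcript length (adjusted p = 0.0476), and cuticle genes at a mean of at least 10 (adjusted p = 0.0137 by cameraPR). Digestive enzymes passed as higher with Fisher's exact test of the calls (adjusted p = 0.0117). Of the myogenic and mesoderm regulators, 2 of 11 were higher and 1 lower (3 and 1 adjusted over the list alone). The myogenic factor nau (mikado.phaw_50.283870G303) was at least 16.3-fold higher. The FGF receptor htl (mikado.phaw_50.282543aG111) fell by 3.35 ± 1.04 in the authors' deposited table. Of 19 muscle structure genes 1 rose (1 adjusted over the list alone), tmod (mikado.phaw_50.283355aG275, tropomodulin), by 1.11 ± 0.36 in the authors' deposited table. The following counts are higher and lower, with those adjusted over the list alone in brackets. Cuticle genes had 13 and 6 of 152 (13 and 7), digestive enzymes 9 and 5 of 64 (10 and 6), ribosomal proteins 3 and 0 of 62 (2 and 0), and oxidative phosphorylation 1 and 1 of 30 (1 and 1). Ecdysone genes had 0 and 2 of 30 (0 and 2), synapse genes 0 and 1 of 31 (0 and 1), eye genes 1 and 0 of 19 (1 and 0), and Notch genes 1 and 0 of 8 (1 and 0). None of 8 Wnt genes was called by DESeq2 in either direction, nor with p adjusted over the list alone. Genes of other organisms, models whose best annotation is bacterial, archaeal or viral, had 5 higher and 3 lower of 97 (5 and 3). The median of ecdysone genes was 0.24 although their mean statistic was negative (-0.03), and genes of other organisms had a median of -0.08 with a positive mean statistic (0.15). The called ecdysone genes were CYP315A1 (mikado.phaw_50.283028bG125), of ecdysteroid synthesis, which fell by 1.74 ± 0.54, and Eip74EF (mikado.phaw_50.001137bG325), an ecdysone-response factor, which fell by 2.40 ± 0.79 in the authors' deposited table.

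Of abundant named genes above the floor at both stages, CTLGA1 (mikado.phaw_50.282275aG238), a C-type lectin, fell by 7.62 ± 0.33 and Crc (mikado.phaw_50.282976aG202), annotated as a calreticulin, fell by 7.41 ± 0.49 in the authors' deposited table. The peptidases CTSC (mikado.phaw_50.000135cG187) and Nep2 (mikado.phaw_50.283828dG83) rose by 8.25 ± 0.78 and 7.74 ± 0.82 in the authors' deposited table. VMO1 (mikado.phaw_50.282396aG170), a homologue of a vitelline membrane protein, was at least 2671-fold higher, and PHEX (mikado.phaw_50.283828dG84), a metallopeptidase, at least 239-fold higher. The other model named VMO1 also rose, from a mean of 2385 to 6735, and the log2 change of the summed means of both was 1.98. A model of RPL36 (mikado.phaw_50.282260aG401) was at least 15889-fold higher while the other model of that name fell, so that the log2 change of their summed means was 0.78. A model of MRPS25 (mikado.phaw_50.000318G2) was at least 257-fold lower, and the summed means of both models of that name changed by -0.29 on the log2 scale.

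In all, 1677 genes were higher and 1821 lower at S19 (47.9% higher), by the authors' Wald test with an adjusted p under 0.05 among 33913 genes. Among genes with an eggNOG annotation 51.7% of the calls were higher. None of 22 COG categories passed by cameraPR, 4 of them had an unadjusted p under 0.05, and Fisher's exact test of the calls called 3 higher and 6 lower.

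The second comparison asks what changed between S19 and S21. Genes of appendage patterning, regulators of neurogenesis and 4 of 8 Hox genes rose, hemocyanin and phenoloxidase genes rose, and some muscle proteins were higher. The lists of ribosomal proteins, mitochondrial respiration and cell cycle genes fell, though the COG category of cell cycle control did not pass. The homeobox gene B-H1 (BarH1), which patterns distal limb segments and sensory organs, was among the largest rises. The median log2 fold change of genes with a mean count of at least 100 was -0.19, so list medians are also given relative to this shift.

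Of 15 tested appendage patterning genes, 9 rose and none fell (9 and 0 adjusted over the list alone), with a median log2 change of 1.36, or 1.55 relative to the shift, and adjusted p = 1.16e-08 by cameraPR. B-H1 (mikado.phaw_50.282639aG232) was at least 360-fold higher at S21. A second Dll model (mikado.phaw_50.282654bG564) rose by 4.79 ± 0.55 in the authors' deposited table. Neurogenesis regulators rose in 8 of 14 cases with none lower (9 and 0 adjusted over the list alone), with a median of 1.87, or 2.06 relative to the shift, and adjusted p = 5.72e-07 by cameraPR. SCRT2 (mikado.phaw_50.283869fG65), a zinc finger factor of neurons, was at least 29.1-fold higher, and SLIT1 (mikado.phaw_50.283815bG34), a secreted axon guidance protein, at least 18.3-fold higher. The Hox list rose again, with 4 of 8 higher and none lower (5 and 0 adjusted over the list alone) and adjusted p = 0.000236 by cameraPR. In the authors' deposited table abd-A (mikado.phaw_50.282695aG453) rose by 2.31 ± 0.44, Antp by 1.61 ± 0.23, Ubx by 1.36 ± 0.32 and Abd-B by 1.04 ± 0.27. The values of Dfd (1.18 ± 0.51), Scr (0.75 ± 0.40), lab (0.03 ± 0.33) and hoxb3 (1.33 ± 1.44) did not pass in the authors' deposited table.

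Hemocyanin and phenoloxidase genes rose in 5 of 8 cases with none lower (5 and 1 adjusted over the list alone), and adjusted p = 1.88e-07 by cameraPR, or adjusted p = 0.166 with ranks of the statistic. Their median of 5.30, or 5.49 relative to the shift, was 4.88 with genes below the floor at their bound. PPO1 (mikado.phaw_50.283863bG368), a phenoloxidase of cuticle hardening and immunity, rose by 5.69 ± 0.48 in the authors' deposited table. A hemocyanin (mikado.phaw_50.282861dG68) was at least 153-fold higher and a second (mikado.phaw_50.283828aG508) at least 73.7-fold higher. Of 20 muscle structure genes, 4 rose and none fell (4 and 0 adjusted over the list alone), and the list missed the threshold with adjusted p = 0.0524 by cameraPR, or adjusted p = 0.0377 without the members that share only a symbol or a word with it. It also passed with 1 gene model per name (adjusted p = 0.0438) and with the statistic corrected for transcript length (adjusted p = 0.0278 by cameraPR). The myosin light chain Mlc1 (mikado.phaw_50.283815cG631) rose by 6.78 ± 0.81 in the authors' deposited table. Counted against the floor, a troponin C (mikado.phaw_50.015400aG462) was at least 90.2-fold higher. The cell adhesion gene kirre (mikado.phaw_50.283871aG97), of myoblast fusion, rose by 3.22 ± 1.13 in the authors' deposited table, the single called member of 11 myogenic regulators (1 adjusted over the list alone, adjusted p = 0.147 by cameraPR, or adjusted p = 0.0399 with ranks).

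Ecdysone and moulting genes had 8 higher and 2 lower of 33 (9 and 2 adjusted over the list alone), with a median of 0.99, or 1.18 relative to the shift, and adjusted p = 0.0340 by cameraPR. The call was lost with a preset correlation of 0.05 (adjusted p = 0.172) and without the members that share only a symbol (adjusted p = 0.0541 by cameraPR). Cyp18a1 (mikado.phaw_50.282639aG135), which inactivates ecdysteroids, was at least 38.3-fold higher, and CYP307A1 (mikado.phaw_50.283468aG30), of ecdysteroid synthesis, at least 25.5-fold higher. The nuclear receptors Hr46 (mikado.phaw_50.282695dG120) and Hr4 (mikado.phaw_50.007301bG205) were at least 22.3-fold and at least 23.4-fold lower. The Wnt list had adjusted p = 0.0340 by cameraPR and adjusted p = 0.0708 with a preset correlation of 0.05. Fisher's exact test of the higher calls gave it adjusted p = 0.266. Of 8 Wnt genes, 2 were higher and none lower (2 and 0 adjusted over the list alone). These were the ligand Wnt5 (mikado.phaw_50.283862bG76), which rose by 2.14 ± 0.44 in the authors' deposited table, and the receptor FZD10 (mikado.phaw_50.283872cG156), at least 30.2-fold higher. Among Notch genes 1 of 8 rose (1 adjusted over the list alone), the ligand DLL4 (mikado.phaw_50.015400bG155), by 0.88 ± 0.22 in the authors' deposited table, and the list did not pass (adjusted p = 0.705 by cameraPR).

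Cytosolic ribosomal proteins fell in 36 of 62 cases with 1 higher (55 and 1 adjusted over the list alone), with a median of -1.37, or -1.18 relative to the shift, and adjusted p = 1.16e-14 by cameraPR. In the authors' deposited table RPS20 (mikado.phaw_50.283870G396) fell by 4.45 ± 0.43, and RpLP0 (mikado.phaw_50.283867bG90) rose by 1.86 ± 0.66. Oxidative phosphorylation genes fell in 9 of 30 cases with none higher (12 and 0 adjusted over the list alone), with a median of -0.69, or -0.50 relative to the shift, and adjusted p = 1.54e-06 by cameraPR. A model of Ndufa9 (mikado.phaw_50.283828dG121), a subunit of respiratory complex I, fell by 2.10 ± 0.29, and Uqcrc2 (mikado.phaw_50.000081aG22), of complex III, fell by 0.91 ± 0.26 in the authors' deposited table. Cell cycle genes fell in 20 of 60 cases with 4 higher (21 and 4 adjusted over the list alone), with a median of -0.58, or -0.39 relative to the shift, and adjusted p = 0.000476 by cameraPR. Without the members that share only a symbol, 18 of 56 were lower and 3 higher. The related COG categories, tested among annotated genes alone, did not pass. Cell cycle control had a median of -0.28, or -0.09 relative to the shift (adjusted p = 0.758 by cameraPR). Replication and repair had a median of -0.16, or 0.03 relative to the shift (adjusted p = 0.805 by cameraPR). The RfC4 model that had fallen at S19 (mikado.phaw_50.008125G1) rose by 5.19 ± 0.46 and another RfC4 model (mikado.phaw_50.282654bG634) fell by 1.49 ± 0.45 in the authors' deposited table.

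Digestive enzymes were called lower by cameraPR (adjusted p = 0.0457) with 11 higher and 14 lower of 68 (11 and 14 adjusted over the list alone), although their median was 0.10, or 0.29 relative to the shift, and the mean statistic -0.66. The median was 0 with genes below the floor at their bound, and -0.35 among the 35 members with a mean of at least 10. The call was lost with a preset correlation of 0.05 (adjusted p = 0.256), with ranks (adjusted p = 0.520), with the statistic corrected for transcript length (adjusted p = 0.157) and without the members that share only a word with the list (adjusted p = 0.118 by cameraPR). Fisher's exact test of the calls passed the list in both directions, higher (adjusted p = 0.0219) and lower (adjusted p = 0.00337). A carboxypeptidase (mikado.phaw_50.000203aG410) fell by 8.59 ± 1.87 in the authors' deposited table, and a trypsin-like protein (mikado.phaw_50.000135bG253) was at least 87.5-fold higher. The other lists did not pass, with adjusted p from 0.450 for genes of other organisms to 0.893 for cuticle genes by cameraPR. Segmentation genes had 2 higher and 4 lower of 22 (3 and 4 adjusted over the list alone), among them Prd, which fell by 6.12 ± 0.68, and cad (mikado.phaw_50.283872cG186, caudal), a posterior patterning gene, which fell by 3.47 ± 0.55 in the authors' deposited table. With the counts adjusted over the list alone in brackets, synapse genes had 3 higher and 2 lower of 44 (3 and 2), cuticle genes 9 and 12 of 164 (8 and 11), and eye genes 1 and 1 of 28 (0 and 1). Germ cell genes had 1 and 1 of 27 (1 and 1), and genes of other organisms 2 and 13 of 99 (2 and 13). Segmentation genes and genes of other organisms had positive medians (0.47 and 0.33, or 0.66 and 0.52 relative to the shift) with negative mean statistics (-0.15 and -0.21). The chitinase Cht4 (mikado.phaw_50.282976bG116) rose by 6.21 ± 0.71 in the authors' deposited table. The synaptic vesicle protein Syt1 (mikado.phaw_50.282976bG223) was at least 43.2-fold higher and Gad1 (mikado.phaw_50.000148bG148), which makes the transmitter GABA, at least 13.6-fold higher.

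Among the largest changes of single genes, the protease TMPRSS9 (mikado.phaw_50.283868dG4) fell by 10.58 ± 0.65 and a model of the protease CTSC (mikado.phaw_50.000135cG185) fell by 9.70 ± 0.79 in the authors' deposited table. The model of CPT1B (mikado.phaw_50.283817fG284), an enzyme of fatty acid import into mitochondria, was at least 207-fold lower. The ion transporter Ncc69 (mikado.phaw_50.282695gG66) rose by 7.48 ± 0.97 in the authors' deposited table. The MRPS25 model that had been lower at S19 was at least 395-fold higher at S21, and the summed means of both models of that name changed by 0.10 on the log2 scale.

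In all, 3002 genes were higher and 3431 lower at S21 by the authors' Wald test (46.7% higher) among 37222 genes, and with fold changes centred on the shift 3939 were higher and 2582 lower (60.4% higher). The share of calls that were higher was 34.5% among genes with a mean of at least 100 and 34.0% among genes with an eggNOG annotation. Among COG categories, translation (11 higher and 189 lower of 463, adjusted p = 6.54e-11), RNA processing (adjusted p = 0.000126), energy production (adjusted p = 0.000574), nucleotide metabolism (adjusted p = 0.00863) and coenzyme metabolism (adjusted p = 0.0157) fell by cameraPR. Signal transduction rose, with 141 higher and 88 lower of 1655 and adjusted p = 0.0147 by cameraPR. With a preset correlation of 0.05 only 1 category passed by cameraPR. Fold changes also went with transcript length. With genes of a mean of at least 100 in 5 groups by length, the medians were 0.30, 0.26, -0.27, -0.57 and -0.42 from the shortest to the longest. They were 0.10, 0.11, -0.08, -0.22 and -0.22 for S23 against S21.

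The last comparison asks what changed between S21 and S23. Genes of muscle structure rose most, and genes of cuticle and synapses rose as well. Genes of the cell cycle fell in most cases, and ribosomal proteins fell further. Myosin heavy chain, troponin I and myosin light chain, the proteins of the contractile apparatus, were among the largest rises of all named genes.

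Muscle structure genes rose in 12 of 28 cases with 1 lower (12 and 1 adjusted over the list alone) and adjusted p = 8.13e-34 by cameraPR. Their median of 4.37 was 2.33 with genes below the floor at their bound. The troponin I gene wupA (mikado.phaw_50.283866G1) rose by 8.85 ± 0.31 and a myosin regulatory light chain, Mlc2 (mikado.phaw_50.283817fG350), by 9.42 ± 0.33 in the authors' deposited table. Mhc (mikado.phaw_50.283821G36), myosin heavy chain, at 3474925 to 3516494 of scaffold phaw_50.283821, was at least 648-fold higher, and a second Mlc2 model (mikado.phaw_50.283743bG14) at least 444-fold higher. The member that fell was tmod, by 0.43 ± 0.15 in the authors' deposited table, a call lost with fold changes centred on their median (adjusted p = 0.0796). Of 14 myogenic and mesoderm regulators, 2 were higher and 1 lower (2 and 1 adjusted over the list alone), and the list did not pass (adjusted p = 0.781 by cameraPR). Among them kirre rose by 1.05 ± 0.29, and Six4 (mikado.phaw_50.000135eG4), a homeobox factor of mesoderm, fell by 2.27 ± 0.53 in the authors' deposited table.

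Cuticle and chitin genes rose in 57 of 189 cases with 11 lower (63 and 12 adjusted over the list alone), with adjusted p = 2.89e-06 by cameraPR. Their median of 1.49 was 0.96 with genes below the floor at their bound. Among these, 2 chitin-binding proteins (mikado.phaw_50.000203aG80 and mikado.phaw_50.283869bG147) were at least 159-fold and at least 106-fold higher. The chitin deacetylase verm (mikado.phaw_50.282976aG4) fell by 4.99 ± 0.20, and an abundant chitin-binding protein (mikado.phaw_50.015400aG461) fell by 4.73 ± 0.23 in the authors' deposited table. Synapse and neurotransmission genes rose in 15 of 54 cases with 1 lower (18 and 1 adjusted over the list alone), a median of 1.52 and adjusted p = 0.000471 by cameraPR. Complexin (cpx, mikado.phaw_50.283867bG96), which controls vesicle release, was at least 39.6-fold higher, and the glutamate receptor Nmdar2 (mikado.phaw_50.283828bG555) at least 15.6-fold higher. The member that fell, Syn1 (mikado.phaw_50.000135fG429), is a syntrophin and shares only a symbol with synapsin. A model of GluCl (mikado.phaw_50.283468bG19), a glutamate-gated chloride channel, was at least 425-fold higher. There were 13 other models of that name, and the summed means of all of them changed by 2.24 on the log2 scale.

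Hemocyanin and phenoloxidase genes had 3 of 7 higher and 1 lower (3 and 1 adjusted over the list alone), with adjusted p = 0.00584 by cameraPR and adjusted p = 0.174 with ranks of the statistic or adjusted p = 0.154 with 1 gene model per name. Fisher's exact test of the higher calls gave the list adjusted p = 0.119. A hemocyanin (mikado.phaw_50.283828aG506) rose by 3.05 ± 0.28 at a mean of 132448 normalized counts in the authors' deposited table. A PPO1 model (mikado.phaw_50.283863bG343) rose by 4.01 ± 0.32, and another (mikado.phaw_50.283863bG368) fell by 1.27 ± 0.21 in the authors' deposited table.

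Cell cycle genes fell in 45 of 60 cases with 3 higher (48 and 3 adjusted over the list alone), with a median of -1.42 and adjusted p = 6.54e-48 by cameraPR. Of the 3 higher members, 2 were tramtrack (ttk), a zinc finger factor that shares only a symbol with the kinase TTK. The gene GINS4 (mikado.phaw_50.000203bG214), of the replication fork, fell by 2.67 ± 0.67 in the authors' deposited table. Counted against the floor, a low-count model of MCM3 (mikado.phaw_50.283823aG10), of the replicative helicase, was at least 7.19-fold lower, a call lost with centred fold changes (adjusted p = 0.0529). Ribosomal proteins fell in 42 of 62 cases with 1 higher (50 and 1 adjusted over the list alone), with a median of -0.68 and adjusted p = 3.30e-17 by cameraPR. RpLP0 fell by 4.45 ± 0.32 and a model of RpL7A (mikado.phaw_50.282639bG34) rose by 2.03 ± 0.74 in the authors' deposited table. Oxidative phosphorylation genes fell in 8 of 30 cases with none higher (8 and 0 adjusted over the list alone), with adjusted p = 0.00186 by cameraPR, among them Ndufa9 (mikado.phaw_50.283828dG121), by 1.70 ± 0.17 in the authors' deposited table.

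The Hox list did not pass (adjusted p = 0.781 by cameraPR), with 1 higher and 1 lower of 8 (2 and 1 adjusted over the list alone). In the authors' deposited table abd-A rose by 1.19 ± 0.19 and Dfd (mikado.phaw_50.282695aG472) fell by 1.30 ± 0.37, and the values of Ubx (0.47 ± 0.20), Scr (0.32 ± 0.34), Abd-B (0.25 ± 0.18), hoxb3 (0.17 ± 1.11), Antp (-0.30 ± 0.16) and lab (-0.35 ± 0.26) did not pass. The remaining lists did not pass, with adjusted p from 0.0914 for Wnt and eye genes to 0.781 by cameraPR. Under alternatives, eye genes passed as higher with ranks (adjusted p = 0.00482), and Wnt genes with ranks (adjusted p = 0.0287) and with the statistic corrected for transcript length (adjusted p = 0.0435 by cameraPR). Appendage genes passed as higher with 1 gene model per name (adjusted p = 0.0148) and at a mean of at least 10 (adjusted p = 0.0487 by cameraPR). Neurogenesis regulators had 0 higher and 3 lower of 14 (1 and 3 adjusted over the list alone), among them neur, which fell by 1.04 ± 0.15, and ato (mikado.phaw_50.007301cG221, atonal), a proneural factor of sense organs, which fell by 0.96 ± 0.34 in the authors' deposited table. With the counts adjusted over the list alone in brackets, appendage genes had 4 higher and 0 lower of 15 (4 and 0), Wnt genes 3 and 0 of 8 (4 and 0), Notch genes 2 and 2 of 9 (3 and 2), and segmentation genes 2 and 1 of 22 (2 and 0). Dll (mikado.phaw_50.282654bG562) rose by 0.69 ± 0.11, FZD10 by 2.01 ± 0.52 and odd (mikado.phaw_50.000289bG166), a zinc finger gene of segments and leg joints, by 1.93 ± 0.44 in the authors' deposited table. The cloned Parhyale odd lies on another model (mikado.phaw_50.000289bG177), which fell by 0.56 ± 0.21 in the authors' deposited table. The ligand DLL4 fell by 0.80 ± 0.11 in the authors' deposited table.

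Ecdysone genes had 7 higher and 3 lower of 36 (7 and 3 adjusted over the list alone), and 1 of the higher ones, Burs (mikado.phaw_50.283823cG563), a subunit of the hormone bursicon that acts on the new cuticle, was at least 44.1-fold higher. Hr4 was at least 103-fold higher. A Cyp18a1 model (mikado.phaw_50.283826G852) fell by 3.97 ± 0.32 in the authors' deposited table. Germ cell genes had 1 higher and 3 lower of 27 (0 and 2 adjusted over the list alone), among them nanos (mikado.phaw_50.283872aG14), named for a translational repressor of germ cells, which fell by 3.18 ± 0.82 in the authors' deposited table. The cloned Parhyale nanos lies on another model (mikado.phaw_50.007301aG91), with a mean of 0 in this comparison in the authors' deposited table. Digestive enzymes had 12 higher and 13 lower of 80 (12 and 13 adjusted over the list alone), and genes of other organisms 12 and 3 of 101 (10 and 3). Segmentation genes had a median of -0.05 with a positive mean statistic (0.38). Of 39 eye genes 5 were higher and none lower (4 and 0 adjusted over the list alone). All 5 share only a word with the list, such as receptors of the rhodopsin family, and none of the 19 other members was called by DESeq2 in either direction.

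**Figure D3:**
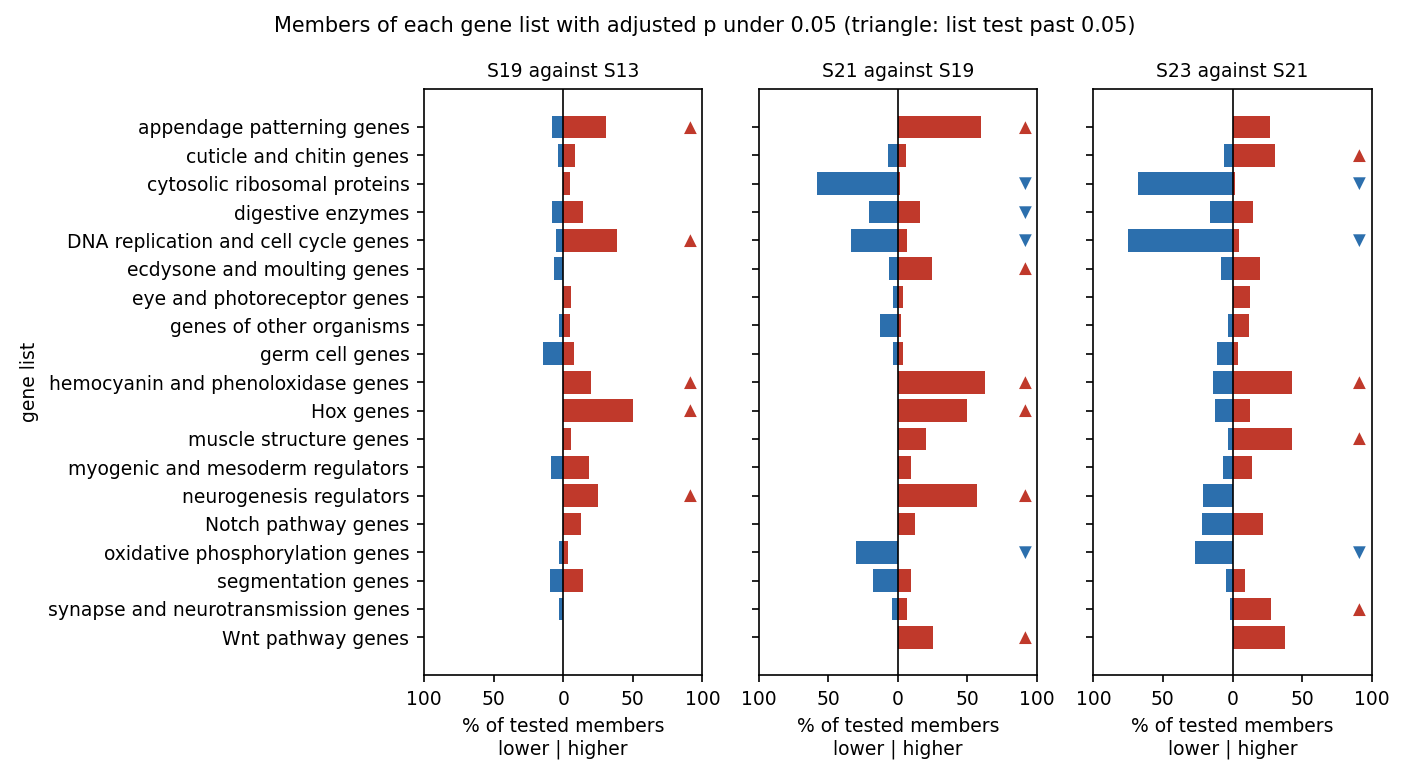
Share of the tested members of each gene list (y axis) that passed an adjusted p of 0.05 by DESeq2, in % (x axis, red higher and blue lower at the later stage), with 1 panel per pair of stages. Triangles mark lists past 0.05 by cameraPR, pointing up or down. Cell cycle genes went from 23 of 60 higher at S19 against S13 to 45 of 60 lower at S23 against S21.

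Among the largest changes of single genes, CTLGA1 (mikado.phaw_50.282275aG238) rose by 8.36 ± 0.17 in the authors' deposited table. TFPI2 (mikado.phaw_50.000203bG425), a protease inhibitor, fell by 7.95 ± 0.60 and PRSS2 (mikado.phaw_50.283868dG6), a serine peptidase, fell by 5.93 ± 0.55 in the authors' deposited table. A model of Sod2 (mikado.phaw_50.283826G137), mitochondrial superoxide dismutase, was at least 235-fold lower, and the summed means of the 5 models of that name changed by -0.27 on the log2 scale. The CPT1B model that had been lower at S21 was at least 254-fold higher at S23. No other model has that name, so sharing of reads could not be examined for it. The lectin CTLGA3 (mikado.phaw_50.001137aG42) fell by 5.64 ± 0.18 and the tubulin TUBA3C (mikado.phaw_50.283811G55) fell by 5.42 ± 0.23 in the authors' deposited table.

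In all, 4672 genes were higher and 3854 lower at S23 by the authors' Wald test (54.8% higher) among 43330 genes. The balance turned among genes with a mean of at least 100, where 1754 of 4447 calls were higher (39.4%), and among genes with an eggNOG annotation, where 1962 of 4253 were (46.1%). The share was 59.8% with centred fold changes and 63.3% with a log2 fold change of at least 1 as well. Among COG categories, extracellular structures (28 higher and 3 lower of 87, adjusted p = 5.07e-05), cytoskeleton (adjusted p = 7.72e-05) and signal transduction (adjusted p = 0.0107) rose by cameraPR. RNA processing (adjusted p = 7.44e-06), translation (adjusted p = 1.69e-05), cell cycle control (adjusted p = 1.69e-05), chromatin structure (adjusted p = 2.49e-05) and replication and repair (adjusted p = 0.000295) fell by cameraPR. With a preset correlation of 0.05 none of the 22 categories passed by cameraPR, while 9 had an unadjusted p under 0.05 at 0.01 and Fisher's exact test of the calls called 3 higher and 7 lower.

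Genes were also followed through consecutive intervals. Those called in both of the first intervals went most often up at S19 and down at S21, with 557 genes against 176 expected of independent lists. Another 429 genes fell in both (168 expected), 249 fell and then rose (106 expected) and 187 rose in both (111 expected). Between the second and last intervals the largest group was that of 1040 genes that fell in both (341 expected). It was followed by 554 that rose in both (243 expected), 505 that rose and then fell (317 expected) and 366 that fell and then rose (261 expected). Among genes with a mean of at least 100 there was no such excess of opposite changes, with 297 that rose and then fell (322 expected) and 174 that fell and then rose (171 expected). Among named genes, a model of MRPS25 (mikado.phaw_50.000318G2) fell and then rose over the first intervals. The other model of that name moved the opposite way each time. The summed means of both models changed by only -0.29 and then 0.10 on the log2 scale. The lectin CTLGA1 fell at S21 and rose at S23, and abd-A rose at both. Between the first and last intervals, which share no libraries, 494 genes rose and later fell (182 expected), 316 fell in both (189 expected), 205 fell and later rose (132 expected) and 174 rose in both (128 expected). At a mean of at least 100 these were 324 (177 expected), 176 (197 expected), 123 (64.5 expected) and 76 (57.9 expected), so the excess that fell in both did not hold there.

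Across 9909 genes with a mean of at least 100, the log2 fold changes of the first and second intervals had Pearson's r of -0.213 and Spearman's rho of -0.141. The r simulated for a shared stage alone was -0.501, so a negative r can arise from the shared stage. The covariance of these fold changes was -0.335, against -0.104 simulated for a shared stage alone. For the second and last intervals the covariance was -0.0447, against -0.0795 simulated (r = -0.0345 against -0.505 simulated, rho = 0.108, 10961 genes). For the first and last intervals the covariance was -0.234 (r = -0.185, rho = -0.163, 9438 genes). Genes are not independent replicates, so these values describe the tables.

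The annotation part of the data asks how far the Mikado gene models improve on earlier ones. Mikado gave 49780 genes with 53935 transcripts, of which 32.6% had a single exon and 79.5% had both untranslated regions. The assemblies of the 4 stages supplied 9714 transcripts, 18.0% of the total, with 3597 from S23 and 1740 from S13. An orthology annotation was found for 36.1% of Mikado genes (95% interval 35.6 to 36.5, 17947 of 49780). It was found for 21.2% of MAKER genes (20.9 to 21.6, 10707 of 50440). The MAKER file lists mRNAs for only part of its genes (14893 mRNAs), so the share for MAKER is a lower bound if the other genes were not searched.

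Positions were used for 30721 Mikado loci, 61.7% of the genes, so shares of earlier models that overlap a Mikado locus are lower bounds. A Mikado locus overlapped 46.0% of 50440 MAKER genes on the same strand (45.6 to 46.4) and 63.2% of 42214 transcript alignments of Kao and co-workers (62.7 to 63.7). It overlapped 34.8% of 247131 alignments of the earlier transcriptome (34.6 to 34.9), and 53.8% on either strand. Of 142 alignments of cloned sequences, 120 were overlapped (84.5%, 77.5 to 90.0). Mikado itself took 8426 transcripts from those of Kao and co-workers and 31 from cloned sequences, so overlap with these sets is partly built in. In the other direction, 82.1% of the Mikado loci with a position overlapped a MAKER gene and 71.9% a transcript of Kao and co-workers. Of the same loci, 62.7% overlapped the earlier transcriptome and 0.316% a cloned sequence. The positions came from a list that pairs Mikado loci with 28596 distinct MAKER loci, so the share of 82.1% may be partly set by that pairing. These shares need not hold for the genes without a position.

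Splice junctions numbered 422645, of which 183637 passed Portcullis (43.4%, 43.3 to 43.6). Passed junctions held 82.5% of the spliced alignments, with a median of 16 reads against 2 for those that did not pass. Canonical splice motifs were found at 81.4% of passed junctions and 64.1% of the others. Among junctions with at least 10 reads, 79.7% passed.

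The peak files, whose assay is not given in the sources used here, listed 196871 merged regions with a median width of 494 bases. Of these, 29.2% were distal intergenic (29.0 to 29.4), 27.3% of the type gene (27.1 to 27.5), 9.07% promoter, 6.80% proximal intergenic and 6.01% exon. Each region has a single type, so the type gene leaves out regions typed as exon or untranslated region and is not the full share within genes. A further 17.6% were of unknown type. Distal regions had a median distance of 52135 bases to the nearest gene. Among genes with an adjusted p in all 3 intervals, those called in at least 1 had a promoter region in 44.7% of cases (4779 of 10691), against 34.6% of genes not called (7354 of 21255), an odds ratio of 1.53 with p = 2.08e-68 by Fisher's exact test (two-sided). This test treats genes as independent. Among those whose highest mean over the 3 comparisons was at least 100, the shares were 46.0% and 34.4% (p = 5.78e-47 by Fisher's exact test).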

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

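No paired analysis was possible because the deposited tables hold the authors' comparisons and no values per library. For the same reason size factors other than those of DESeq2, a low-count filter per library, a fit with the replicate letter, the leaving out of each replicate and other splits of the samples were not run, and the effect of depth per library is unknown. No list, category or named gene called as designed turned its direction, but the balance of called genes did. The share of calls that were higher went from 47.9% to 51.7% for S19 against S13 among annotated genes, and from 46.7% to 60.4% for S21 against S19 with centred fold changes, where it was 34.5% at a mean of at least 100 and 34.0% among annotated genes. For S23 against S21 it went from 54.8% to 39.4% at a mean of at least 100 and to 46.1% among annotated genes, but to 59.8% with centred fold changes and to 63.3% with a log2 fold change of at least 1 as well. Of 342 tests of single lists, 314 kept their side of the threshold, 12 passed only under the alternative and 16 passed only as designed, and of 330 tests of COG categories 308 did, with 8 and 14 that did not. These totals leave out Fisher's exact test of the calls. With it, neurogenesis and hemocyanin genes at S19, Wnt genes at S21 and hemocyanin genes at S23 lost their calls. Digestive enzymes passed as higher with it at S19 and at S21. Of 796 values of named genes, 757 kept their side of the threshold, 37 lost their call, of which 28 at an adjusted p under 0.01, and 2 passed only under the alternative. The alternative within 10 kb removes distal regions and those without a gene by definition, so they have no value under it.

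The number of called genes followed the threshold and the genes tested. At an adjusted p under 0.01, by construction stricter, 2309 genes were called for S19 against S13 (1110 higher, 1199 lower) and 4258 for S21 against S19 (1899 higher). With a log2 fold change of at least 1 as well, 2305 genes were lower at S23 than at S21. Among genes with a mean of at least 100, so with fewer genes, 1959 were called for S19 against S13 (807 higher, 1152 lower), 3887 for S21 against S19 (1342 higher) and 4447 for S23 against S21 (1754 higher). Among genes with an eggNOG annotation the calls were 1638 (847 higher, 791 lower), 3182 (1082 higher, 2100 lower) and 4253 (1962 higher, 2291 lower) in the order of the stages.

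With a preset correlation of 0.05, 3 lists were called higher for S19 against S13 in place of 5. For COG categories of S19 against S13, Fisher's exact test called 3 higher and 6 lower, and a mean of at least 10 gave 1 lower, in place of 0. For S21 against S19, 2 categories were higher with ranks, with 1 gene model per name, with a mean of at least 10 and with Fisher's exact test, in place of 1. Fisher's exact test called 8 lower in place of 5. With the correlation of 0.05 it was 0 higher and 1 lower, and for S23 against S21 it was 0 higher and 0 lower. A larger correlation widens the null by construction, and for the other moves the cause was not tested.

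Overlaps of S19 against S13 and S21 against S19 at an adjusted p under 0.01 were 123 genes higher in both, 339 higher then lower, 146 lower then higher and 260 lower in both, and with a mean of at least 100 they were 72 higher in both (66.0 expected), 358 higher then lower (205 expected) and 100 lower then higher (65.7 expected). For S21 against S19 and S23 against S21 they were 336, 276, 202 and 615 in the same order at an adjusted p under 0.01, and with a mean of at least 100 they were 196 higher in both (111 expected), 297 higher then lower (322 expected) and 174 lower then higher (171 expected). With a log2 fold change of at least 1 as well, 426 were lower in both. Fewer genes pass each of these by construction.

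With an e-value under 1e-10 the share of annotated genes was 32.1% for Mikado and 18.2% for MAKER, and per transcript it was 39.3% for Mikado. With 50% of the earlier locus covered, a stricter rule, a Mikado locus overlapped 40.6% of MAKER genes, 59.0% of the transcripts of Kao and co-workers and 32.1% of the earlier transcriptome. In the other direction, of the Mikado loci with a position, these were 57.3%, 60.2% and 52.7%. On either strand, a looser rule, they were 49.0%, 67.7% and 53.8%, and in the other direction 95.5%, 80.7% and 73.7%, with 0.420% for cloned sequences. The shares of Mikado loci that overlapped a MAKER gene, 57.3% and 95.5%, may be partly set by the pairing of loci described above. Of junctions with at least 10 reads 79.7% passed, and of canonical junctions 49.4%. In the higher-score 50% of peak regions, 26.9% were distal, 4.61% exon, 23.1% gene, 9.42% promoter, 6.18% proximal and 25.7% of unknown type, and the cause was not tested. Within 10 kb of a gene, with fewer regions in the total, 11.3% were exon, 51.2% gene, 17.0% promoter and 12.8% proximal.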

Other observations

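Of 30 gene models whose transcript was taken from a cloned Parhyale sequence, a group chosen after its values were seen, 8 were higher and 3 lower at S19, 9 higher and 1 lower at S21, and 3 higher and 7 lower at S23. The model of the clone hes4 (mikado.phaw_50.282654bG580) had log2 values of 4.13 ± 0.48, 0.87 ± 0.25 and -2.44 ± 0.24 in the order of the stages in the authors' deposited table. The model of knirps (mikado.phaw_50.283866G145) had 4.71 ± 0.55, -2.01 ± 0.23 and 1.38 ± 0.17 in the authors' deposited table. The model of runt2 (mikado.phaw_50.283028bG14) rose by 5.32 ± 0.68 at S21, and that of runt1 (mikado.phaw_50.283868bG35) fell by 2.03 ± 0.72 at S19 in the authors' deposited table. The model of collier (mikado.phaw_50.283865bG1) was at least 96.1-fold higher at S21. The model of wntc (mikado.phaw_50.282396bG51) rose by 2.76 ± 0.61 at S23 in the authors' deposited table. The clones named early and late distalless lay on separate models, of which the early one rose at S19 and S23 and the late one at S21.

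The tests below had their predictions written before the test was run, apart from that of the size factors, which was chosen after its result was seen. For the first test, the count per gene and the question of which sums were free to move were also chosen after the result was seen. Counts of calls and the genes with the largest changes had been seen before all of them. Some of the named genes with the largest changes among those with a mean of at least 100 were below 1 mean normalized count in 1 of the stages compared. Members named for their list alone were not in this test. If reads of similar models had moved between models of one name, the sum over those models would change little. Of 10 such genes 6 had another model of the name, and for 3 of these 6 (RPL36, MRPS25 and Sod2) the sum changed by less than 1 on the log2 scale. For MRPS25 and Sod2 the other models were too abundant for the sum to move by that much, so of the 4 genes left to decide only RPL36 kept its sum, and sharing cannot be told apart from other causes for these genes. No biological explanation was tested.

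Cytosolic ribosomal proteins were lower at S21 than at S19, with a median log2 change of -1.37. After centring on the median of genes with a mean of at least 100 it was -1.18, so the list fell relative to these genes. The centring could move the list only by that median, -0.19, so it cannot decide whether the size factors play a part. Genes of other kinds matched to the list on transcript length and mean had a median of -0.55. It lay above the list's by 0.827 (95% bootstrap interval 0.720 to 0.977, 310 genes), so length and mean together do not account for all of the list's fall. The match does not separate length from mean. In the 5 groups of genes by length the medians were 0.30, 0.26, -0.27, -0.57 and -0.42 from the shortest to the longest. Short transcripts as a group therefore did not fall. The bootstrap treats genes as independent and does not cover the spread between libraries. No biological explanation was tested.

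Genes changed in both the first and second intervals more often than independent lists would, in the same direction (429 lower in both against 168 expected) as well as in opposite ones (557 higher then lower against 176 expected). Across all 9909 genes with a mean of at least 100 in both tables, called or not, the covariance of the fold changes was -0.335 (95% bootstrap interval -0.437 to -0.242), below every value simulated for unchanged groups that share a stage (-0.119 to -0.0959). Chance values of the shared stage therefore may account for part of this covariance only. The simulation takes its spread from the deposited standard errors. No biological explanation was tested.

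A first hypothesis was that genes of regulatory lists have more peak regions assigned than genes of housekeeping lists. The 68 regulators had a mean of 19.9 regions (SD 24.4) and the 148 housekeeping genes 3.28 (SD 4.39), a difference of 16.6 with permutation p = 1e-05, the smallest possible with 100000 permutations. For distal regions alone the means were 5.10 and 1.17 (permutation p = 0.00027). Gene length and the space around each gene were not controlled, so these could account for the difference of 16.6.

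A second hypothesis was that genes whose model came from the S23 assembly rise towards S23. Their median log2 change from S21 to S23 lay 0.528 above that of genes from the S21 assembly (permutation p = 0.0001, the smallest possible with 10000 permutations). Of 3113 such genes 417 were higher and 99 lower at S23. Models assembled from a stage are likely to be those abundant in it, so the difference of 0.528 may reflect how the annotation was built.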
